A study of Homo sapiens with 32 samples.

How the data were processed

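RNA was measured in bone marrow cells sorted as CD141Hi, CD1c or CD34 from 6 healthy donors and 5 patients with myelodysplastic syndromes (MDS), in 32 libraries. Per the protocol in the labels, fewer than 100 cells per library were sorted straight into tubes, complementary DNA was made with the SMART-Seq v4 Ultra Low Input kit, and Nextera XT libraries were read on a NextSeq instrument. The labels do not give the antibodies or gates of the sort. CD141, CD1c and CD34 are the proteins of the genes THBD, CD1C and CD34.

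The deposited file holds raw counts per gene, 1 column per library, for 58037 genes under versioned Ensembl identifiers. Its values are whole numbers with no scaling. Per the submitters' processing notes, reads were handled with CASAVA 1.8.2, TopHat2 2.0.13, Picard 1.97 and HTSeq 0.6.1 on the build GRCh38. Their settings, the strand setting and the annotation release are not given in the sources used here, so reads at overlapping, antisense or pseudogene loci are uncertain in origin. Positions and gene classes came from GENCODE release 29 (GRCh38) by unversioned identifier, which matched 57433 genes (98.959%). Y-linked genes, XIST and TSIX, 563 entries in all, were left out of the tests and levels of genes and gene lists, which left 57474. The measures per library (total counts, genes with a count and shares of counts) include them. Copies made by PCR cannot be told from molecules in these counts, so depth gives counting error only.

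Groups were the disease status and cell type of the labels. Counts were scaled with TMM factors, genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15, minimum share 0.7), and the remaining 36695 genes were fitted in 1 quasi-likelihood model of the 6 groups with robust estimates of spread in edgeR 4.0.16 under R 4.3.3. The 12 contrasts were the 3 MDS against healthy comparisons, the 3 comparisons of cell types within each disease group, and the 3 differences of the MDS effect between cell types. All tests were two-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. Log2 fold changes carry a prior count of 0.125, so the fitted value of a gene whose libraries are at or near 0 in 1 group depends on that setting. Where a named gene had no count in 1 group, a lower bound of the ratio is given instead, with 3 counts over that group as the limit. With 1 to 3 counts the ratio of mean CPM to those counts is given with a 95% Poisson interval of the counts. These bounds and intervals cover counting error in the group with few counts only. They take the mean of the other group as exact, and spread between donors and copies made by PCR are not covered. The ± after a log2 fold change is its standard error from the same model, and a ± after a level in CPM (counts scaled to the library size) is the standard deviation between libraries.

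For 33 gene lists, camera of limma 3.58.1 tested on log2 CPM from voom whether members moved more than the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Each list test was run again with a correlation estimated from the data. The adjusted p quoted for a list is that of the preset correlation unless the estimated one is named. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

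Named genes followed a rule with 3 parts. The first part takes, for each comparison, up to 12 genes higher and 12 lower with the smallest p among those past the threshold, with an absolute log2 fold change of at least 1 and a count in at least 75% of the libraries of the higher group. The second takes up to 4 members of each list that is described, by smallest p, whether or not they passed. The third takes 13 sorting and lineage genes in every comparison. Genes with common germline deletions or copy number differences, immunoglobulin and T cell receptor segments, and entries without a gene name were not named. Some genes that met the rule are not reported here. The groups, contrasts, gene lists, naming rule and most alternatives were set before the data were examined.

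Per-library measures (total counts, genes with a count, share of counts in the 100 most abundant genes, share in mitochondrially encoded mRNA) were compared between disease groups by exact permutation tests of group means, two-sided, with adjustment over 12 tests in SciPy 1.17.1 under Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9. The labels number healthy donors and patients. Libraries with the same number were taken as from 1 person within a disease group. Their log2 CPM, after removal of group means, correlated across genes by 0.451 on average in healthy donors (18 pairs, against -0.0554 between donors). It was 0.253 without the healthy donor set apart below, and 0.179 in patients (13 pairs, against -0.0448 between patients). Libraries of a healthy donor and a patient with the same number, different people, also correlated, by 0.103 (12 pairs, against -0.0153 for different numbers). The correlation alone thus does not establish 1 person. No library was a copy of another in its group, since the lowest chi-square per degree of freedom between a pair was 123. The fit was tested on simulated data, drawn from the means and spread of the real libraries with 100 genes changed at each size. It recovered 24% to 39% of genes changed 16-fold and 0% to 6% of those changed 4-fold, so most 4-fold changes are missed with these numbers of libraries. Only genes above the median abundance were changed, and the draw used 1 mean profile for all libraries and no donor effect. Unchanged genes were 4 of 29 calls for MDS against healthy CD141Hi cells and 5 of 30 for CD34 cells with all libraries. In the other runs 0 to 2 unchanged genes were called.

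Alternatives set beforehand were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, no filter, a minimum count of 50, the number of genes detected as a covariate, limma-voom with quality weights and the donor as a random effect, only the 2 groups compared, the donor as a replicate block, and leaving out each library in turn. After the data had been seen, 1 healthy donor was set apart by the breadth of its counts, and libraries were found to fall in 2 classes by their share of counts in processed pseudogenes, with a boundary at 0.5%. Every count was therefore also computed without that donor's 3 libraries, without the 5 libraries with counts in the most genes, with the class as a term and within each class. Without that donor 25421 genes passed the filter. For each comparison the count was also taken in 40 splits of the libraries, the real one included.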

Results

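Counts of RNA were obtained for 32 libraries of sorted bone marrow cells, each from fewer than 100 cells. CD141 and CD1c mark the conventional dendritic cell types cDC1 and cDC2, and CD34 marks stem and progenitor cells. The 6 healthy donors gave 6 libraries of each cell type. The 5 patients with MDS gave 4 CD141Hi, 5 CD1c and 5 CD34 libraries, with all 3 cell types from 4 of them. The series concerns the enzyme LSD1, encoded by KDM1A, and how CD141Hi dendritic cells form from MDS progenitors. The labels name no treatment of these cells, and a word in most MDS titles that could bear on it is not explained there. Total counts per library ran from 4.12 to 111 M, with a median of 28.1 M (M, mega).

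Libraries differed widely in breadth. The 3 libraries of 1 healthy donor held 4.12 to 4.70 M counts, yet had counts in 43812 to 49009 genes, with 67.9% to 70.4% of counts in protein-coding genes. The other 29 libraries held 16.4 to 111 M counts in 14135 to 51829 genes, with 85.3% to 97.1% in protein-coding genes. TMM factors of that donor's libraries were 2.32 to 2.43, against 0.666 to 1.32 in the others. Counts without those 3 libraries, a set chosen after the data had been seen, are therefore given too. In CD141Hi cells, genes with a count averaged 18206 ± 3068 in MDS (SD, n = 4) and 32144 ± 10213 in healthy donors (SD, n = 6; exact permutation p = 0.00952, adjusted p = 0.114). The corresponding means were 24689 and 35066 in CD34 cells (exact permutation p = 0.0606, adjusted p = 0.242) and 28411 and 36686 in CD1c cells (exact permutation p = 0.165, adjusted p = 0.494). None of the 12 exact permutation tests of library measures passed after adjustment. With 4 against 6 libraries no single test in CD141Hi cells could pass alone after it, so this does not show that breadth is alike. There every MDS library had counts in fewer genes (at most 21259) than every healthy one (at least 21872). The share of counts in processed pseudogenes lay above 0.5% in the libraries of 3 healthy donors and 4 patients and below it in those of 3 healthy donors and 1 patient.

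**Figure D1:**
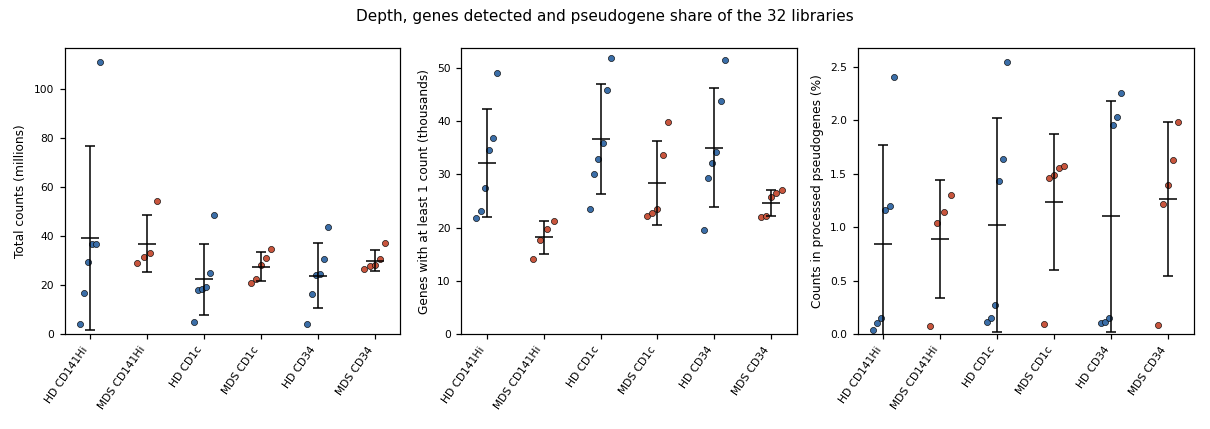
Each point is 1 library of healthy donors (HD) or patients (MDS), the panels plot total counts, genes with a count and the percentage of counts in processed pseudogenes, and bars are means with the standard deviation. The 3 libraries of 1 healthy donor are the lowest of their groups in total counts, at 4.12 to 4.70 M.

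Group means of the sorting genes followed the cell type labels, while single libraries did not all do so. Another cell type's sorting gene had more counts than the label's own in 2 of 6 healthy and 2 of 4 MDS libraries of CD141Hi cells, in 1 of 6 and 1 of 5 of CD1c cells, and in 0 of CD34 cells. In CPM, THBD and CD34 stood at 3.26 and 63.1 (the donor set apart) and at 46.6 and 114 in the 2 healthy CD141Hi libraries. In 1 of the MDS ones they stood at 124 and 168. The other had THBD at 39.3 and CD1C at 274, with FCER1A at 1825, CLEC9A at 10.0, XCR1 at 0, CLEC10A at 9.13 and IRF8 at 1443. CD1C and CD34 stood at 0.272 and 54.4 in the healthy CD1c library (the donor set apart) and at 106 and 191.5 in the MDS one. All were kept as labelled. THBD, which encodes CD141, averaged 161 ± 118 CPM in healthy CD141Hi cells (SD, n = 6), 32.9 ± 25.9 in CD1c cells and 1.51 ± 1.3 in CD34 cells. The MDS means were 125 ± 90.6 (n = 4), 8.27 ± 6.78 (n = 5) and 5.37 ± 6.91 (n = 5). CD1C averaged 294 ± 214 CPM in healthy and 669 ± 389.7 in MDS CD1c cells, 3.78 ± 3.47 and 81.9 ± 129.5 in CD141Hi cells, and 0.221 ± 0.319 and 2.62 ± 4.48 in CD34 cells. The stem cell antigen CD34 averaged 189 ± 99.9 and 267 ± 96 CPM in healthy and MDS CD34 cells, 31.1 ± 47.4 and 60.8 ± 79.1 in CD141Hi cells, and 19.1 ± 19.1 and 41.9 ± 83.7 in CD1c cells. CLEC9A, a receptor that marks cDC1, stood at 323 ± 226 and 262 ± 298 CPM in healthy and MDS CD141Hi cells, and at 0.933 ± 1.71 and 0.542 ± 1.08 in CD1c cells. KDM1A averaged 80.9 ± 62, 52.7 ± 46 and 101 ± 57.9 CPM in healthy CD141Hi, CD1c and CD34 cells, and 57.7 ± 46.5, 94.2 ± 75.5 and 159.5 ± 90.3 in MDS. GFI1, a repressor that recruits LSD1, averaged 6.2 ± 5.2 and 13 ± 10.6 CPM in healthy and MDS CD34 cells.

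On GRCh38 the 13 sorting and lineage genes, all annotated as protein-coding, lie as follows. THBD (ENSG00000178726.6, chromosome 20, 23045633 to 23049741), CLEC9A (ENSG00000197992.6, chromosome 12, 10030677 to 10066027), XCR1 (ENSG00000173578.7, chromosome 3, 46017024 to 46027742), BATF3 (ENSG00000123685.8, chromosome 1, 212686418 to 212699985), IRF8 (ENSG00000140968.10, chromosome 16, 85898803 to 85922609), CD1C (ENSG00000158481.12, chromosome 1, 158289786 to 158293630) carry markers or regulators of the dendritic cell types. FCER1A (ENSG00000179639.10, chromosome 1, 159289714 to 159308224), CLEC10A (ENSG00000132514.13, chromosome 17, 7074537 to 7080307), IRF4 (ENSG00000137265.14, chromosome 6, 391739 to 411447), CD34 (ENSG00000174059.16, chromosome 1, 207880972 to 207911402) do the same or mark progenitors. KIT (ENSG00000157404.15, chromosome 4, 54657918 to 54740715), KDM1A (ENSG00000004487.15, chromosome 1, 23019443 to 23083689) and GFI1 (ENSG00000162676.11, chromosome 1, 92474762 to 92486876) are the stem cell factor receptor, LSD1 and its partner.

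**Figure D2:**
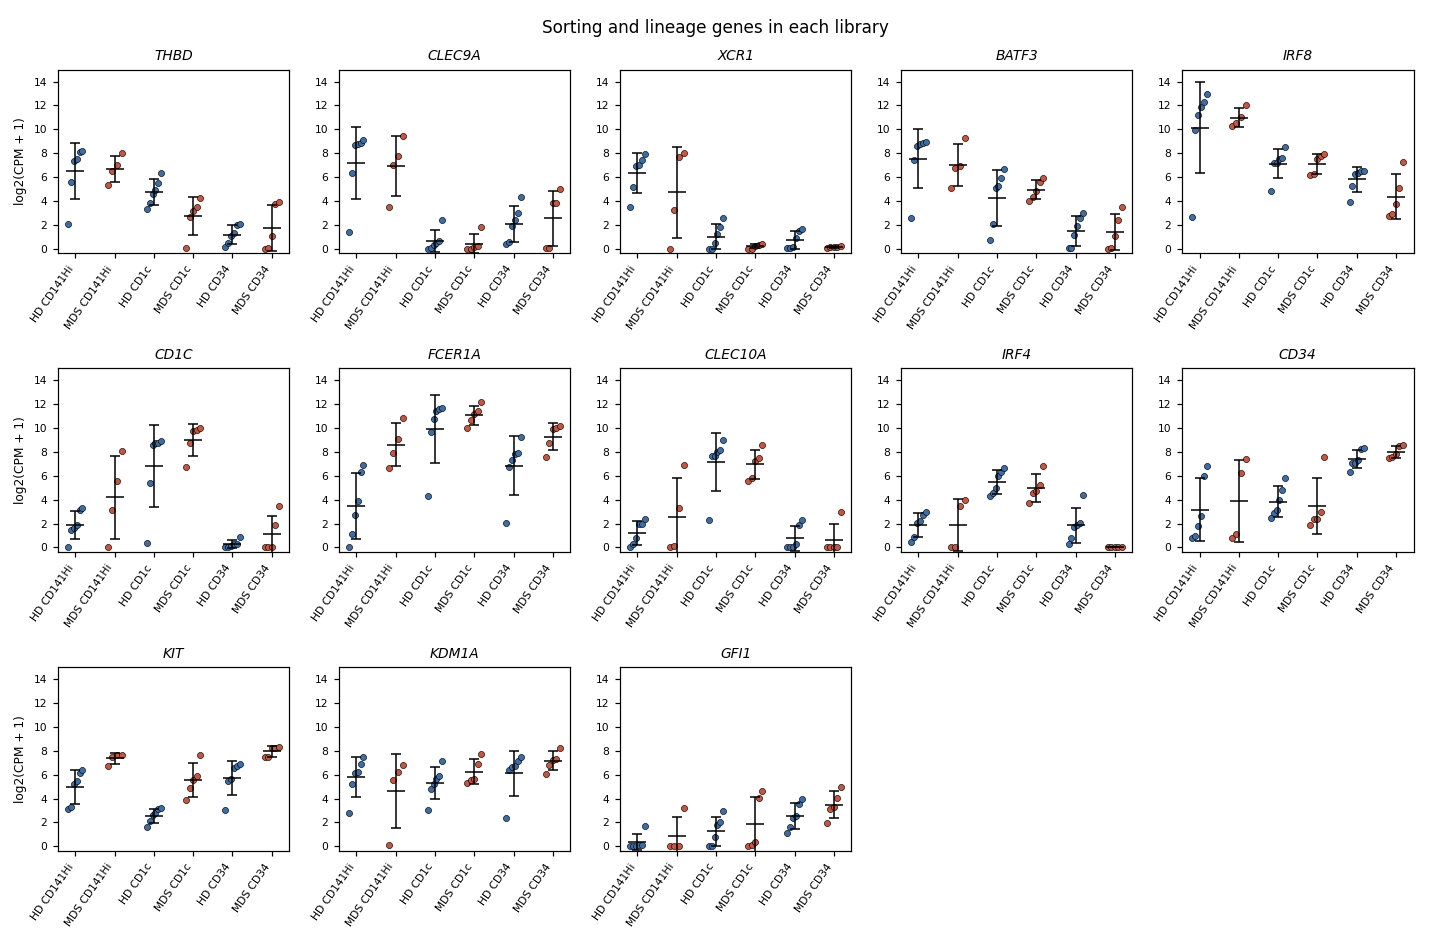
Each point is 1 library and bars are means with the standard deviation on the log2 scale, for the 13 sorting and lineage genes by group, and the vertical axis is log2 of CPM plus 1. THBD had its highest group mean in healthy CD141Hi cells (161 CPM) and CD1C in MDS CD1c cells (669 CPM).

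How CD141Hi cells differ from CD34 progenitors was asked first in healthy donors (6 libraries each). The cDC1 list was higher in CD141Hi cells, with all 25 of its 25 measured genes above 0 and a median log2 fold change of 5.83. The list test passed (adjusted p = 3.24e-95, and 1.46e-06 with an estimated correlation), and the list mean was higher in 6 of 6 donors. Of the members, 14 passed over all genes and 23 adjusted over the list alone. IRF8, the transcription factor that sets the cDC1 fate, was higher by 5.70 ± 0.91 (log2 fold change with its approximate standard error, here and below, adjusted p = 0.00015). So were THBD by 6.72 ± 1.37 (0.0118), the chemokine receptor XCR1 by 7.16 ± 1.63 (0.0425) and BATF3 by 6.95 ± 1.54 (0.0388). WDFY4, needed for cross-presentation, CPNE3 and CAMK2D were higher by 4.78, 3.69 and 5.46. CLEC9A at 5.83 ± 1.73 did not pass (0.268).

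Antigen presentation genes were higher as well. Of 18 MHC class II genes, 17 lay above 0, 7 passed over all genes and 14 adjusted over the list alone (adjusted p = 8.09e-29, and 0.0059 with an estimated correlation). Among them were HLA-DMB (4.12 ± 0.77), HLA-DPB1 (4.37 ± 0.85), HLA-DPA1 (4.48 ± 0.86) and the ubiquitin ligase MARCH1 (4.75 ± 0.98). In the MHC class I and cross-presentation list 22 of 24 members lay above 0, 2 passed over all genes and 9 adjusted over the list alone. The peptide transporter TAP1 was higher by 4.30 ± 0.81. That list call (adjusted p = 7.98e-15) was lost in all libraries, at adjusted p = 0.0552 with an estimated correlation, but not without 1 healthy donor (0.000217). Pattern recognition receptors were higher (17 of 23, 3 past the threshold over all genes, 5 higher and 1 lower adjusted over the list alone). Their list test gave adjusted p = 4.59e-11, and 0.00597 with an estimated correlation. The Toll-like receptor adaptor MYD88 stood at 4.08 ± 0.78, CLEC7A at 4.90 ± 0.97 and UNC93B1 at 3.87 ± 0.80. DC maturation genes were higher (15 of 20, adjusted p = 2.24e-06, and 0.0063 with an estimated correlation). Of these 1 passed over all genes and 2 adjusted over the list alone, with CD83 higher by 5.44 ± 0.92. DC development regulators passed with the preset correlation (16 of 26, adjusted p = 6.47e-06), a call lost at adjusted p = 0.066 with an estimated correlation. Of these, 4 passed over all genes, and 7 higher and 1 lower adjusted over the list alone. BCL6 stood at 3.98 ± 0.82 and ID2 at 3.79 ± 0.89.

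Among the 12 genes with the smallest p were SAMHD1, a deoxynucleotide hydrolase, the kinase LRRK2, thymidine phosphorylase TYMP, the sulfatase SULF2, S100A10, HLA-DQB2, the actin-binding COTL1 and KCTD12, at log2 fold changes from 4.50 to 5.74 and adjusted p from 0.00015 to 0.000404. All 6 CD141Hi libraries lay above the CD34 median for 5 of the 12. With the donor as a block S100A10 did not pass (0.236). Progenitor genes were lower as lists. All 25 of 25 stem and progenitor markers lay below 0 (adjusted p = 3.87e-37, and 0.0059 with an estimated correlation, lower in 6 of 6 donors). Of these 0 passed over all genes and 0 adjusted over the list alone. MLLT3 stood at -2.20 ± 0.84 and CD34 at -2.60 ± 1.27. Granule genes of granulocyte-monocyte progenitors (15 of 16 below 0, adjusted p = 5.84e-13, and 0.0274 with an estimated correlation), basophil and mast cell genes (14 of 15, adjusted p = 2.11e-11 and 0.0149) and B lineage genes (19 of 21, 2.36e-11 and 0.0159) were lower too, with no single member past the threshold. Some cDC2 genes were higher too (15 of 20, adjusted p = 1.00e-08, and 0.0388 with an estimated correlation). Over all genes 2 of them passed and 3 adjusted over the list alone, NDRG2 by 4.88 ± 0.87 and the decoy receptor IL1R2 by 5.09 ± 1.27. Unfolded protein response genes lay above 0 in 16 of 20, and HERPUD1 at 3.17 ± 0.73 and EDEM1 at 3.07 ± 0.73 were the 2 that passed, by either count. Their list call (adjusted p = 3.54e-06) was lost at adjusted p = 0.145 with an estimated correlation. Genes of p53 and apoptosis passed (16 of 24 above 0, adjusted p = 2.69e-06, and 0.0193 with an estimated correlation). Over all genes 0 passed and 1 adjusted over the list alone, with GADD45B at 3.34 ± 0.93 (0.141).

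In all, 126 genes were higher and 0 lower in healthy CD141Hi than CD34 cells, 366 and 17 without the donor set apart, and 207 and 9 with the donor as a block. The count was 284 without that donor's CD141Hi library alone, 76 without 1 other CD141Hi library, and 49 and 77 without each of 2 CD34 libraries.

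In healthy CD1c cells against CD34 cells (6 libraries each), all 20 of 20 cDC2 markers lay above 0, with a median log2 fold change of 4.38 (adjusted p = 3.40e-41, and 5.09e-05 with an estimated correlation). The list mean was higher in 6 of 6 donors. Of these genes, 3 passed over all genes and 19 adjusted over the list alone. CD1C itself was higher by 10.52 ± 2.22 (0.0415, and 0.0818 with the donor as a block), IL1R2 by 7.01 ± 1.38 (0.0036) and the integrin ITGAX by 4.41 ± 0.94 (0.0147). FCER1A at 3.14 ± 1.20, CLEC10A at 7.77 ± 2.24 and IRF4, a transcription factor of cDC2, at 3.42 ± 1.06 did not pass. Monocyte genes were higher (19 of 21, adjusted p = 1.37e-24, and 0.000891 with an estimated correlation). Of these 2 passed over all genes and 13 adjusted over the list alone, with MNDA at 5.09 ± 0.91 and lysozyme, LYZ, at 3.31 ± 0.78 (0.0393, and 0.0675 without the donor set apart). Pattern recognition receptors were higher as a list (20 of 23, 0 over all genes and 7 adjusted over the list alone, adjusted p = 2.07e-15, and 0.000891 with an estimated correlation).

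MHC class II genes were higher in CD1c cells with the preset correlation (15 of 18, 2 over all genes and 15 adjusted over the list alone, adjusted p = 1.90e-13). HLA-DMB was higher by 3.39 ± 0.74 and MARCH1 by 4.20 ± 0.95. The list call was lost at adjusted p = 0.0556 with an estimated correlation. Genes of the AXL SIGLEC6 dendritic cell were higher as a list (9 of 10, 1 over all genes and 1 adjusted over the list alone, adjusted p = 0.000177, and 0.0495 with an estimated correlation). AXL itself at 2.65 ± 1.21 did not pass. Among the 12 genes higher with the smallest p were properdin, CFP, the Fc receptor chain FCER1G, cathepsin H, CTSH, the kinase FGR and ANXA2 next to SAMHD1, TYMP, KCTD12, S100A10, COTL1 and SULF2, at log2 fold changes from 4.27 to 6.24. With the donor as a block FGR (0.0639) and S100A10 (0.32) did not pass.

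Progenitor genes were lower in CD1c cells. All 25 of 25 stem and progenitor markers lay below 0 (adjusted p = 8.75e-55, and 0.000891 with an estimated correlation, lower in 6 of 6 donors). Of these 1 passed over all genes and 20 adjusted over the list alone. KIT, the stem cell factor receptor, was lower with a log2 fold change of -3.69 ± 0.75 (0.00604). MEIS1 at -3.54 ± 1.04 passed adjusted over the list alone only, as did AVP, 3023-fold lower (837 to 24960.3, 2 counts) with the 95% interval from the few counts of the lower group and their number in brackets here and below. The cell cycle kinase CDK6 (-4.13 ± 0.80), FAM117A (-4.11 ± 0.88) and C1orf186 (-3.38 ± 0.81) were lower and kept their calls with the donor as a block. Within the high class by pseudogene share alone 0 genes passed in this comparison. ZNF22 (-3.43 ± 0.83), GAMT (-4.18 ± 1.01), PRKCQ-AS1 (-4.39 ± 1.03) and SCAMP1-AS1 (-4.47 ± 1.07) did not pass with the donor as a block (0.13, 0.193, 0.125 and 0.0838). The last 2 are antisense genes, whose reads are uncertain in origin without the strand. Granule genes of granulocyte-monocyte progenitors were lower as a list (13 of 16, adjusted p = 6.80e-12, and 0.0495 with an estimated correlation). CTSG stood at -6.85 ± 2.37 and ELANE at -7.32 ± 2.73. With the preset correlation erythroid (17 of 22, adjusted p = 7.79e-10), megakaryocyte and platelet (10 of 17, 0.00107) and proliferation genes (21 of 30, 0.00384) were also lower. These calls were lost at adjusted p = 0.0925, 0.0655 and 0.613 with an estimated correlation. In these 4 lists 0 members passed, over all genes or adjusted over the list alone, in edgeR.

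Counted over all genes, 56 were higher and 9 lower in healthy CD1c than CD34 cells, 226 and 52 without the donor set apart, and 139 and 29 with the donor as a block. Leaving out single libraries gave 20 to 70 genes. 8 of the 12 libraries, 2 of CD1c and 6 of CD34 cells, lowered the count by over 1.5 times, to between 20 and 40.

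Between the dendritic cell types of healthy donors, CD141Hi cells had higher cDC1 markers than CD1c cells (25 of 25 above 0, median log2 fold change 3.95, higher in 6 of 6 donors). Their list test gave adjusted p = 8.56e-65, and 4.06e-05 with an estimated correlation, with 1 member past the threshold over all genes and 22 adjusted over the list alone. That 1 gene was the copine CPNE3 (4.01 ± 0.76, adjusted p = 0.0271). IRF8 at 4.25 ± 0.84 (0.0614) and the adhesion gene CADM1 at 5.40 ± 1.15 (0.186) passed only without the donor set apart (0.0187 and 0.00694), and KIT at 2.98 ± 0.73 (0.192) likewise (0.00965). The cDC2 markers were lower (18 of 20, 0 over all genes and 7 adjusted over the list alone, adjusted p = 5.65e-14, and 0.0156 with an estimated correlation). FCER1A, the Fc receptor for IgE, stood at -5.80 ± 1.36, CD1C at -6.28 ± 1.84 and IRF4 at -3.92 ± 1.08. Monocyte genes were lower (20 of 21, 0 over all genes and 1 adjusted over the list alone, adjusted p = 1.77e-12, and 0.0281 with an estimated correlation). CSF1R stood at -3.37 ± 1.06. DC maturation genes were higher in CD141Hi cells (13 of 20, 0 and 2 by the same counts, adjusted p = 6.80e-06, and 0.0156 with an estimated correlation). MARCKSL1 stood at 2.93 ± 0.78 (0.00217 without the donor set apart).

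Genes of MHC class I and cross-presentation lay above 0 in all 24 of 24 members in CD141Hi against CD1c cells (0 over all genes and 3 adjusted over the list alone, adjusted p = 9.28e-11). TAP1 stood at 3.27 ± 0.77 and TAPBP at 1.78 ± 0.64. That call was lost at adjusted p = 0.198 with an estimated correlation, and held without the donor set apart (0.00111). Nuclear genes of oxidative phosphorylation lay above 0 in 30 of 37 (adjusted p = 7.05e-06, and 0.639 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. Over all genes 1 was higher and 0 lower in edgeR, 18 and 5 without the donor set apart, and 4 and 6 with the donor as a block. The count was 7 without that donor's CD141Hi library, 2 without each of 3 other libraries, and 0 without each of the remaining 8.

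The same comparisons were made among MDS cells. CD141Hi cells of 4 patients had higher cDC1 markers than CD34 cells of 5 (24 of 25 above 0, median log2 fold change 5.06, higher in 4 of 4 patients). The list test gave adjusted p = 2.80e-64, and 4.62e-05 with an estimated correlation, with 11 members past the threshold over all genes and 23 adjusted over the list alone. CADM1 was higher by 10.12 ± 1.57 (0.000568), ZNF366 by 11.26 ± 1.92 (0.00238), XCR1 by 10.14 ± 2.04 (0.0135), IRF8 by 5.76 ± 1.01 (0.00101) and WDFY4 by 4.60 ± 0.91 (0.00238). THBD at 4.55 ± 1.37 passed with the donor as a block only (0.105 without and 0.0394 with it). BATF3 at 6.15 ± 1.65 (0.0769) passed only without the healthy donor set apart (0.0332), and CLEC9A at 4.53 ± 1.81 in neither. The cDC2 markers were higher (18 of 20, adjusted p = 1.86e-16, and 0.0117 with an estimated correlation). Of these 3 passed over all genes, and 11 higher and 1 lower adjusted over the list alone, with IRF4 at 7.61 ± 1.47 (0.00221, and 0.127 with the donor as a block) and NDRG2 at 5.04 ± 0.98. CD1A was 644-fold higher (178 to 5318, 2 counts). IRF4 had counts in 2 of 4 CD141Hi libraries.

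MHC class II genes were higher in MDS CD141Hi cells (17 of 18, 4 over all genes and 14 adjusted over the list alone, adjusted p = 1.03e-23, and 0.0134 with an estimated correlation). The lysosomal protease LGMN stood at 6.42 ± 1.06, MARCH1 at 5.26 ± 1.11, HLA-DPB1 at 3.57 ± 0.91 and HLA-DMB at 3.06 ± 0.82. Pattern recognition receptors were higher (18 of 23, 3 and 5 by the same counts, adjusted p = 3.28e-08, and 0.019 with an estimated correlation). CLEC7A, the receptor for fungal glucans, stood at 7.29 ± 1.21 and TLR8 at 9.60 ± 1.90. Among the 12 genes with the smallest p, the kinase LRRK2 (6.86), PARM1 (9.63), the activating receptor CD226 (7.63), the chemokine CXCL16 (8.14), the proton-sensing receptor GPR65 (5.31), KCTD12 (5.12) and NCALD (7.15, 0.0601 with the donor as a block) were higher than the CD34 median in all 4 libraries. So was the antiplasmin gene SERPINF2, 3117-fold higher (863 to 25741, 2 counts). T and NK cell genes lay above 0 in 23 of 26 (1 over all genes, 2 higher and 1 lower adjusted over the list alone), and CD5 was 2800.2-fold higher (503 to 110603, 1 count). Their list call (adjusted p = 0.00121) was lost at adjusted p = 0.451 with an estimated correlation.

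Megakaryocyte and platelet genes were lower in MDS CD141Hi than CD34 cells (13 of 17, 4 over all genes and 6 adjusted over the list alone, adjusted p = 2.74e-05, and 0.0209 with an estimated correlation, lower in 4 of 4 patients). SELP, which encodes P-selectin, and GP9 had no count in the 4 CD141Hi libraries. Taking 3 counts over the group as a limit, they were at least 1684-fold and 388-fold lower than the CD34 mean, by counting error alone. The CD34 means were 42.3 ± 59.7 and 9.75 ± 14.7 CPM (SD, n = 5), with adjusted p of 0.00431 and 0.0292. By the same limit NAP1L3, DNAJC3-AS1, CABLES1 and PGBD2 were at least 1003-fold, 607-fold, 491-fold and 412-fold lower. SLAIN1 (-9.72 ± 1.92), the kinase MAST4 (-6.63 ± 1.48) and the chemokine CXCL3 (-9.08 ± 1.98) were lower too. TIGD1 was 3459.6-fold lower (621 to 136646, 1 count), HSDL1 1558-fold lower (279.7 to 61555, 1 count) and OCRL 659-fold lower (183 to 5445, 2 counts). Basophil and mast cell genes were lower (14 of 15, adjusted p = 4.43e-12, and 0.0162 with an estimated correlation). Of these 1 passed over all genes, and 9 lower and 1 higher adjusted over the list alone. MS4A2, a chain of the IgE receptor, was 2826-fold lower (507 to 111605, 1 count). The list's median was -6.52, and -5.70 with 4 genes that had no CD141Hi count set at their limit. Stem and progenitor markers lay below 0 in all 25 of 25 (1 over all genes and 1 adjusted over the list alone, adjusted p = 2.70e-18), a call lost at adjusted p = 0.0525 with an estimated correlation.

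Over all genes 135 were higher and 107 lower in MDS CD141Hi than CD34 cells, 335 and 246 without the healthy donor set apart, and 120 and 131 with the donor as a block. The share of calls that were higher was 55.8%, and 82.2% with DESeq2 size factors, which called 152 genes. Leaving out single libraries gave 92 to 338 genes. 4 of the 9 lowered the count by over 1.5 times, 1 of CD141Hi (92) and 3 of CD34 cells (128, 145 and 159).

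MDS CD1c cells had higher cDC2 markers than MDS CD34 cells (5 libraries each, 20 of 20 above 0, median log2 fold change 6.48, higher in 5 of 5 patients). The list test gave adjusted p = 3.74e-38, and 9.15e-05 with an estimated correlation, with 5 members past the threshold over all genes and 16 adjusted over the list alone. IRF4 was higher by 10.35 ± 1.61 (0.000134), and ITGAX by 5.41 ± 1.08 (0.00654). IL1R2 was 2021-fold higher (363 to 79834, 1 count) with an adjusted p of 0.000777, and the lipid-presenting CD1B 1531-fold higher (524 to 7424, 3 counts) with 0.00632. CD1C at 7.99 ± 2.17 (0.13) did not pass. Monocyte genes were higher (20 of 21, 1 and 9 by the same counts, adjusted p = 3.35e-23, and 0.0023 with an estimated correlation), with MNDA at 4.10 ± 0.95. So were pattern recognition receptors (22 of 23, 2 and 3, adjusted p = 2.49e-08, and 0.0171 with an estimated correlation), with CLEC7A at 6.51 ± 1.15 and TLR8 at 8.47 ± 1.81. Macrophage genes lay above 0 in 14 of 18 (1 over all genes, 7 higher and 1 lower adjusted over the list alone), with the mannose receptor MRC1 at 7.09 ± 1.77. Their list call (adjusted p = 0.000779) was lost at adjusted p = 0.247 with an estimated correlation. PARM1 (8.35), LRRK2 (5.94), the adaptor SCIMP (6.02), KCTD12 (5.31), the kinase FGR (6.87, 0.076 with the donor as a block), the transporter SLC15A3 (8.83) and SULF2 (5.35) were among the 12 higher genes with the smallest p. So were CD5, 2866-fold higher (514 to 113193, 1 count), and PRKCDBP, 3119-fold higher (559.8 to 123197, 1 count).

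Stem and progenitor markers were lower in MDS CD1c cells (25 of 25, 0 over all genes and 2 adjusted over the list alone, adjusted p = 5.25e-44, and 0.0023 with an estimated correlation), with MEIS1 at -4.12 ± 1.17. So were megakaryocyte and platelet genes (12 of 17, 2 and 3 by the same counts, adjusted p = 3.45e-06, and 0.0145 with an estimated correlation). SELP (-8.40 ± 1.94) did not pass with the donor as a block (0.167). The transcription factor MYCN (-7.91 ± 1.90), the fatty acid transporter SLC27A2 (-8.56 ± 1.76), CYYR1 (-8.99 ± 1.65), HYAL3 (-6.77 ± 1.41), HDHD3 (-6.11 ± 1.32) and MTERF2 (-4.56 ± 1.09) were lower with and without the block. KDELC1 (0.076), the serotonin receptor HTR1F (0.0578) and C3orf80 (0.165) lost their calls with the block, and PCYT2 (0.0692) without the healthy donor set apart. In all, 75 genes were higher and 15 lower, 163 and 25 without that donor, and 140 and 36 with the donor as a block. The count was 181 without 1 CD1c library, 54 without another, and 31, 33 and 42 without each of 3 CD34 libraries.

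Between MDS CD141Hi (n = 4) and CD1c cells (n = 5), cDC1 markers were higher in CD141Hi cells (24 of 25 above 0, median log2 fold change 3.85, higher in 4 of 4 patients). The list test gave adjusted p = 2.20e-49, and 0.000305 with an estimated correlation, with 1 member past the threshold over all genes and 17 adjusted over the list alone. CADM1 was higher by 7.58 ± 1.41. XCR1 at 9.71 ± 2.01 (0.0592) and IRF8 at 3.85 ± 0.93 (0.0699) did not pass. Lower were CXCL3 (-10.23 ± 2.06), the mannose receptor MRC1, 3413-fold lower (612 to 134790.2, 1 count), GPRC5C, 1349.7-fold lower (242 to 53310.3, 1 count), and adenylate kinase AK5, 1502-fold lower (416 to 12401, 2 counts). So was the monocyte receptor CD300E, which had none and was at least 998-fold lower. All 6 named genes that passed had an adjusted p of 0.0452. Over all genes 2 were higher and 5 lower, 2 and 1 without the healthy donor set apart, and 2 and 2 with the donor as a block, where of the named genes GPRC5C alone passed (0.0246). Single libraries moved the count to 0 to 49: without 1 CD141Hi library it was 0, 3, 40 and 49 in turn, and it was 2, 4, 12 and 18 without 4 of the CD1c libraries.

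MDS cells were then set against healthy cells of the same type. The median log2 fold change over all genes was -3.27 in CD141Hi, -1.84 in CD1c and -1.81 in CD34 cells, and -0.39, -0.40 and -0.22 without the donor set apart, so values here are read against those medians. With edgeR, 0 genes passed in any of the 3 cell types, where 16514, 5580 and 13193 genes had an unadjusted p below 0.05 and chance would give 1835. Much of that excess came with single libraries. Without the library of the donor set apart alone, of the same cell type, the numbers were 5887, 2132 and 6284, where chance would give 1644, 1656 and 1672. In CD141Hi cells leaving out any other library gave 14400 to 17132. Without 1 other healthy library the number was 3288 in CD1c and 7961 in CD34 cells, where chance would give 1749 and 1724. Without single MDS libraries it ran from 3137 to 8981 in CD1c cells. DESeq2 called 274 higher and 12506 lower in CD141Hi cells, 36 and 1165 in CD1c cells, and 50 and 8401 in CD34 cells, and without the donor set apart 200 and 1110, 24 and 87, and 48 and 1918. limma-voom called 7 and 116, 1 and 4, and 4 and 15. The 0 of edgeR depended on the fit. With the class by pseudogene share as a term it called 133 and 11053 genes in CD141Hi, 0 in CD1c, and 28 and 6141 in CD34 cells, and with that term and without the donor set apart 0, 1 and 0. With the number of genes detected as a covariate it called 102 and 24 in CD141Hi cells and 0 in the others, and with no filter 67, 14 and 3. Without the donor set apart edgeR called 0 genes in CD141Hi and CD34 cells and 1 in CD1c cells, where the progenitor marker KIT was higher in MDS by 3.80 (adjusted p = 0.0134, against 3.71 ± 0.77 and 0.164 in all libraries). Stem and progenitor markers, KIT among them, were higher in MDS CD1c cells as a list (21 of 25 above 0, 0 over all genes and 1 adjusted over the list alone, adjusted p = 0.00553, and 0.494 with an estimated correlation), a call that ended without the donor set apart (0.0835) and, with that donor kept, without 1 MDS library (0.934). BAALC stood at 5.51 ± 2.21 and HOPX at 3.29 ± 1.40, neither past the threshold. KIT lay above the healthy median in 5 of 5 MDS CD1c libraries and CD34 in 1 of 5, so progenitors among the sorted cells may add to the list in 1 library. In each cell type KIT was higher in every MDS library than in every healthy one. The lowest MDS and highest healthy values were 103 and 84 CPM in CD141Hi, 13.4 and 8.02 in CD1c, and 173 and 117 in CD34 cells. Where the KIT call comes from was not tested. No list call in these comparisons held with an estimated correlation.

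In CD141Hi cells, cDC1 markers had a median log2 fold change of -0.57 and lay below 0 in 23 of 25, with 0 past the threshold over all genes and 0 adjusted over the list alone. Against the lower median of all genes the list test pointed up and did not pass (adjusted p = 0.336), so median and test differ in sign. Without the donor set apart the list was lower past the threshold (median -0.81, adjusted p = 3.85e-10, and 0.322 with an estimated correlation). That call ended without 1 MDS library (adjusted p = 0.065). By library, the cDC1 mean was 4.03 ± 1.28 in MDS (SD, n = 4) and 5.28 ± 0.79 in healthy donors (SD, n = 5) in log2 CPM above all genes. Here 2 of 4 MDS libraries lay below every healthy one (exact permutation p = 0.111, adjusted p = 0.524). TLR3, the sensor of double-stranded RNA, stood at -3.14 ± 1.19 (0.06), THBD at -0.36 ± 1.20, CLEC9A at -0.31 ± 1.58, XCR1 at -0.03 ± 1.38, BATF3 at -0.57 ± 1.35, IRF8 at -0.56 ± 0.84 and KDM1A at -0.49 ± 0.86.

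Markers of other cells were higher in MDS CD141Hi libraries as lists. Erythroid genes lay above 0 in 21 of 22 (0 past the threshold over all genes, 2 adjusted over the list alone, adjusted p = 8.24e-14, and 0.217 with an estimated correlation). By library the list mean lay above every healthy one in 1 of 4. The globin genes HBB and HBM stood at 4.38 ± 1.78 and 4.98 ± 2.16. Monocyte genes were higher as a list (18 of 21, 0 over all genes and 1 adjusted over the list alone, adjusted p = 5.86e-08, and 0.217 with an estimated correlation). The cDC2 markers were too (15 of 20, 0 over all genes, 1 higher and 1 lower adjusted over the list alone, adjusted p = 2.60e-07, and 0.217 with an estimated correlation). By library these list means lay above every healthy one in 1 and 2 of 4. Among their genes stood CSF1R at 3.59 ± 1.12, LYZ at 2.13 ± 0.79, FCER1A at 4.24 ± 1.31, CD1C at 4.43 ± 1.74 and IL1R2 at -7.20 ± 1.70, none past the threshold. Cytosolic ribosomal protein genes (71 of 83, adjusted p = 5.39e-31, and 0.221 with an estimated correlation) and mitochondrial mRNA (13 of 13, 1.71e-12 and 0.217) were higher against all genes with 0 members past the threshold. Immediate-early genes, which handling of cells can raise, were higher against all genes too (10 of 22 above 0, 0 over all genes and 4 higher adjusted over the list alone, adjusted p = 1.29e-05, and 0.221 with an estimated correlation), a call that ended without the donor set apart (0.213) and turned to lower with the number of genes detected as a covariate. EGR1 stood at 3.07 ± 0.90, HSPA1A at 3.46 ± 1.06, HSPA1B at 4.57 ± 1.46 and JUN at 2.37 ± 0.81. Without the donor set apart the ribosomal median was 0.01. The TNF and NF-kB list (19 of 25 below 0, 0 over all genes, 3 lower adjusted over the list alone, adjusted p = 0.728) passed as lower without that donor only (adjusted p = 0.0326, and 0.419 with an estimated correlation). Its member CXCL3 stood at -6.02 ± 1.73. Neutrophil genes (15 of 19 below 0, 0 over all genes, 8 lower and 1 higher adjusted over the list alone, adjusted p = 0.36) and stromal and endothelial genes (14 of 18, 0 and 9 lower, 0.448) did not pass. Their medians of -4.97 and -4.65 became -4.05 and -4.04 with genes at 0 in MDS set at their limit.

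CD1c cells of patients also had higher erythroid genes (20 of 22 above 0, 0 over all genes and 2 adjusted over the list alone, adjusted p = 9.78e-09, and 0.159 with an estimated correlation). By library 3 of 5 lay above every healthy one. HBD stood at 4.28 ± 1.96 and HBM at 6.10 ± 2.23. Immediate-early genes were higher against all genes (15 of 22, 0 past the threshold by either count, adjusted p = 2.15e-07, and 0.159 with an estimated correlation), with EGR1 at 1.95 ± 0.84. So were interferon-stimulated genes (24 of 30, 0 past the threshold by either count, adjusted p = 2.47e-08, and 0.127 with an estimated correlation). IFITM3, which blocks viral entry, stood at 2.27 ± 0.78 and IFIT1 at -4.68 ± 1.87. Members of LSD1 complexes and their partners were higher as a list (12 of 17, 0 past the threshold by either count, adjusted p = 0.000172, and 0.127 with an estimated correlation). ZMYM2 stood at 1.24 ± 0.68 and KDM1A at 0.84 ± 0.79. Plasma cell genes (9 of 12, adjusted p = 0.00185, and 0.127 with an estimated correlation) had a median of 0.92 with edgeR but -0.27 with voom, with the immunoglobulin joining chain JCHAIN at 3.92 ± 1.75. By library they were 0.82 log2 units higher, above every healthy library in 4 of 5 (exact permutation p = 0.00866, adjusted p = 0.286). Glycolysis and hypoxia genes had a median of -0.35 and a mean of -0.45 but tested as higher against all genes (adjusted p = 0.0149, and 0.419 with an estimated correlation). Without the donor set apart the list test pointed down (0.605). Of the lineage genes CD1C stood at 1.19 ± 1.53, FCER1A at 0.30 ± 1.16, IRF4 at -0.33 ± 1.01 and CLEC10A at -0.59 ± 1.75, none past the threshold.

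In CD34 cells of patients, IRF4 averaged 0.0273 ± 0.0157 CPM (SD, n = 5) against 4.9 ± 7.74 in healthy donors (n = 6), a log2 fold change of -7.26 ± 1.43 that did not pass (0.0559, and 0.203 without the donor set apart). B lineage genes lay below 0 in 18 of 21 (0 over all genes and 2 adjusted over the list alone, adjusted p = 0.0502). They passed as lower without that donor only (adjusted p = 7.64e-05, and 0.357 with an estimated correlation). POU2AF1, a B cell coactivator, stood at -4.57 ± 1.42 and RAG2, of V(D)J recombination, was 136-fold lower (46.6 to 659.7, 3 counts) without passing. The plasmacytoid DC list (15 of 20 below 0, 0 over all genes and 2 adjusted over the list alone) did not pass (0.629), with SPIB at -4.84 ± 1.25. Genes of p53 and apoptosis (19 of 24 above 0, adjusted p = 2.00e-06, and 0.115 with an estimated correlation) and immediate-early genes (18 of 22, 5.30e-05 and 0.372) were higher against all genes. So were genes recurrently mutated in MDS (22 of 28, adjusted p = 1.02e-07, and 0.275 with an estimated correlation) and LSD1 complex members and partners (13 of 17, 5.32e-05 and 0.183). In these 4 lists 0 members passed over all genes. Adjusted over the list alone, SNAI1 (4.96 ± 1.54), a repressor that recruits LSD1, was the only one. TET2, a DNA dioxygenase, stood at 1.92 ± 0.68 (0.0667), PMAIP1 at 1.91 ± 0.82, EGR1 at 1.73 ± 0.84, KIT at 1.90 ± 0.72 (0.0678) and KDM1A at 0.66 ± 0.79 (0.634). The immediate-early call ended without the donor set apart (0.307).

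**Figure D3:**
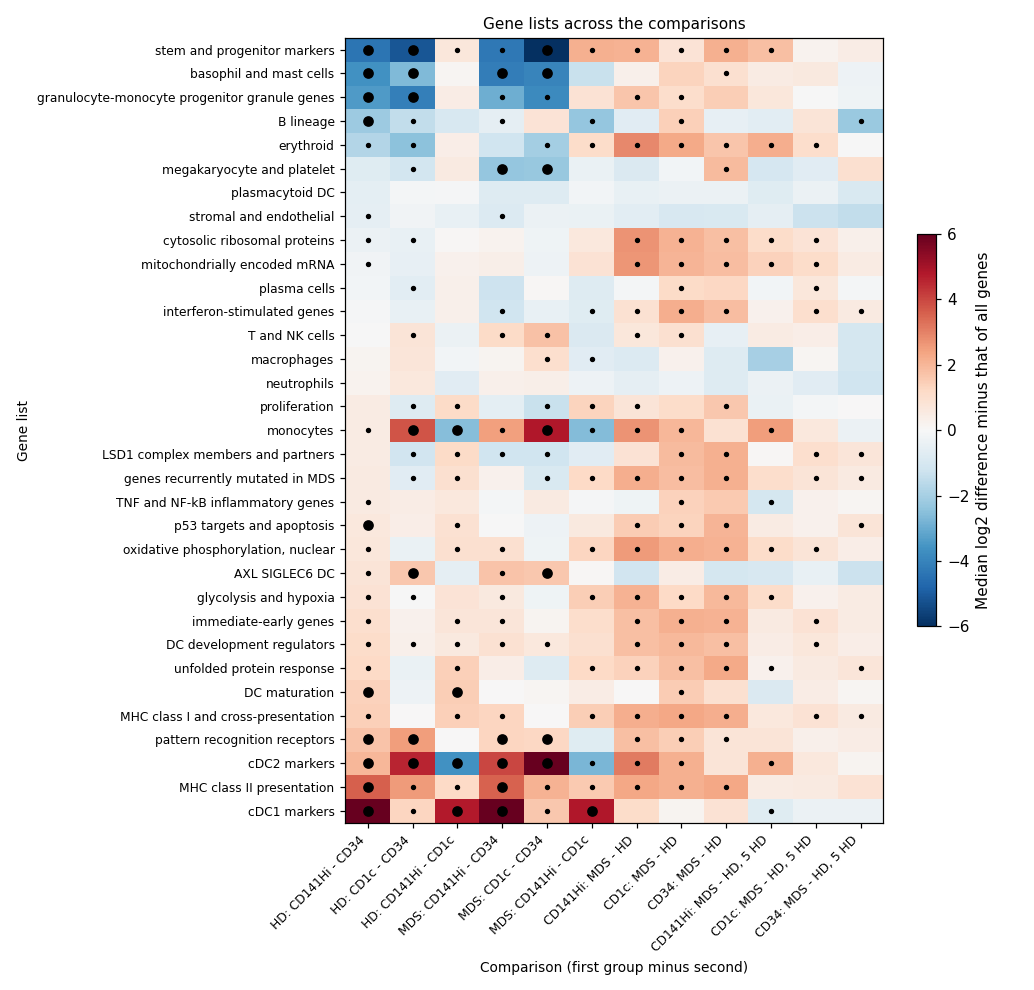
Colour gives the median log2 fold change of each gene list minus that of all genes, for 9 comparisons and for MDS against healthy donors without 1 healthy donor (5 HD), where small dots mark lists past an adjusted p of 0.05 with the preset correlation and large dots those that also passed with an estimated one. The cDC1 list carries large dots in the comparisons of CD141Hi cells with other cell types, and no list carries one between MDS and healthy donors.

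Whether the MDS effect differed between cell types was tested gene by gene. With edgeR 0 genes passed for CD141Hi against CD34, CD1c against CD34, or CD141Hi against CD1c cells, and 0 without the donor set apart, with 2809, 1726 and 3009 genes at an unadjusted p below 0.05. DESeq2 called 516, 94 and 467 genes, 447, 71 and 472 without that donor, and limma-voom 65, 8 and 25. The largest list difference was in B lineage genes, 18 of 21 of which had a higher MDS effect in CD1c than in CD34 cells (adjusted p = 3.72e-09, and 0.0933 with an estimated correlation). Of these 0 passed over all genes and 1 adjusted over the list alone. The B cell gene FCRLA stood at 8.07 ± 2.44, POU2AF1 at 4.66 ± 1.76 and the B cell receptor chain CD79B at 2.78 ± 1.22. No difference in cell type genes between healthy donors and MDS is read from the counts above, since these 0 genes are the test of that difference.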

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

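Chosen only after the result was seen were the test of background reads in the classes by pseudogene share and all 4 tests of the CD141Hi marker lists; the tests of genomic DNA, depth, processed copies and other splits were set before. Of 102 groups of values checked for a library far from the others, 20 had one, where chance gives about 1 in 20, or 5.1, for independent normal values. The genes share the same libraries and many values lie near 0, so the 5.1 is a rough guide only. Total counts of 1 library stood apart in healthy CD141Hi cells (111 M) and in MDS CD141Hi cells (54.2 M). In healthy CD34 cells the same library, of the donor set apart, was far from the others in 2 shares. These were that of the 100 most abundant genes (16.5%) and that of mitochondrial mRNA (1.76%). In healthy CD141Hi cells 1 library stood apart in log2 CPM of CLEC9A (1.37), BATF3 (2.57), IRF8 (2.66) and GFI1 (1.71), and in healthy CD1c cells of CLEC9A (2.44), IRF8 (4.79), FCER1A (4.33) and CLEC10A (2.27). In healthy CD34 cells it did so for CD1C (0.88), FCER1A (2.06) and KDM1A (2.33). Of these 11 values 10 belong to the donor set apart. In MDS, 1 library stood apart for CLEC9A (1.79) and CD34 (7.59) in CD1c cells, for CLEC10A (2.97) and IRF4 (0.00) in CD34 cells, and for GFI1 (3.22) in CD141Hi cells. The other IRF4 values were 0.0401 to 0.0523, so that difference lies at the floor, and CLEC10A was at 0 in all other libraries of its group.

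The MDS effect on gene lists differed between cell types past the threshold with the preset correlation in 32 of 99 tests, and in 0 with an estimated one, where the smallest adjusted p was 0.0933. Values are medians minus that of all genes. In CD141Hi against CD34 cells the difference was positive for cDC2 markers (1.74), monocytes (1.72), T and NK cells (1.02), B lineage (0.90), erythroid (0.84), cytosolic ribosomal protein (0.66), mitochondrial mRNA (0.63) and nuclear oxidative phosphorylation genes (0.35). It was negative for interferon-stimulated genes (-1.21), LSD1 complex members (-1.18), p53 and apoptosis (-1.08), megakaryocyte and platelet (-1.02) and unfolded protein response genes (-0.90). In CD1c against CD34 cells it was positive for B lineage (2.27), cDC2 (1.32), T and NK cell (1.15), macrophage (0.91), plasma cell (0.82), monocyte (0.50) and ribosomal protein genes (0.18), and negative for megakaryocyte and platelet (-0.66), p53 and apoptosis (-0.62), glycolysis (-0.62) and proliferation genes (-0.35). In CD141Hi against CD1c cells it was positive for ribosomal protein genes (0.47) and negative for plasma cell (-1.39), B lineage (-1.24), interferon-stimulated (-0.90), macrophage (-0.78), TNF and NF-kB (-0.76), DC maturation (-0.47) and LSD1 complex genes (-0.33). Without the donor set apart, 17 of the 32 kept their direction past the threshold.

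The counts of 1 healthy donor's 3 libraries were spread over the whole gene annotation. Low sequencing depth is argued against by counts without Y-linked genes, XIST and TSIX. The other 29 libraries thinned to 4695646 counts had counts in at most 41798 genes, below the 43699 to 48885 of the 3. Reads from genomic DNA may account for it: olfactory receptor genes, silent in blood and marrow cells, had counts in 87.7% to 99.2% of 375 members, and across 31934 genes at 0 in most other libraries the count rose with exon length (Spearman rho 0.58 to 0.701). It stays open, because another donor's library reached 99.7%, and 91.2% after thinning, against a thinned median of 7.2%. The design gives no biological group for this donor, so no biological explanation was tested.

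Libraries fall in 2 classes by their share of counts in processed pseudogenes, 1.48 ± 0.301% (SD, 17 libraries without the donor set apart) against 0.12 ± 0.056% (12 libraries), and no donor has libraries in both. Background reads over the genome are argued against, since the ratio of mean lincRNA and antisense shares, high over low class, was 0.958 where that of pseudogene shares was 12.3. Reads of expressed genes counted at their processed copies may account for it: across 940 ribosomal protein pseudogenes the counts followed those of the parent gene with a median rho of 0.143 in the high class and 0.128 in the low class, between the limits of 0.1 and 0.3 set beforehand, which leaves it open, while their median share of pseudogene counts was higher in the high class, as predicted (30.3% against 16.3%). The classes hold 3 and 3 healthy donors and 4 and 1 patients, so a difference between donors or in how reads were placed also stays open, untested.

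In CD141Hi cells without the donor set apart, cDC1 markers were lower and erythroid, monocyte and cDC2 markers higher in MDS as lists with the preset correlation. None of these calls held with an estimated one. With the class by pseudogene share as a term the cDC1 list stayed lower in the list test with the preset correlation (adjusted p = 1.98e-10), as predicted if the class is not the cause. The call without that term did not hold with an estimated correlation, so this cannot decide, and the class stays open. A single patient's library, the 1 of 4 with more CD1C than THBD, may carry the lower cDC1 list, since without that library the call ended (adjusted p = 0.0649, median relative to all genes 0.0002 against -0.72). Spread between donors alone may too (exact permutation p = 0.111, 4 against 5 libraries). Other cells in the CD141Hi gate, a hypothesis, were tested as a rise in markers of every other type. Of 15 such lists 0 were lower past the threshold, 4 were higher and 7 had a median above all genes. This cannot decide it, since other cells need raise only the markers of their own type. It stays open and may overlap with the single library, which had CD1C at 274, FCER1A at 1825 and CLEC9A at 10.0 CPM. There XCR1 stood at 0, but IRF8, also a cDC1 marker, at 1443 CPM. Another MDS library had more CD34 (168 CPM) than THBD (124 CPM). A difference of MDS CD141Hi cells themselves stays open, untested.

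Other splits of the same libraries were compared with the real groups, 40 splits each, the real one included, given as genes in the real split and the highest other. For MDS against healthy donors these were 0 and 15209 in CD141Hi, 0 and 1 in CD1c and 0 and 9308 in CD34 cells. All 40 splits gave as many, as they must where the real number is 0, so they say nothing about chance. The 2 splits with 13793 and 15209 genes in CD141Hi cells and the 1 with 9308 in CD34 cells point to a structure of the samples. They put the donor set apart in the smaller group, but the other splits that do so gave at most 5 and 2, so that donor's place alone does not account for them. In healthy donors the numbers were 126 and 7831 for CD141Hi against CD34 cells (4 splits as large), 65 and 43 for CD1c against CD34 cells (1) and 1 and 3 for CD141Hi against CD1c cells (3). In MDS they were 242 and 82 (1), 90 and 23 (1) and 7 and 33 (12) in the same order. For the differences of the MDS effect they were 0 and 1, 0 and 1 and 0 and 5, with 40 as large in each, which again says nothing about chance. Over all 40 splits only the real one was as large for CD1c against CD34 cells in healthy donors and for CD141Hi and CD1c against CD34 cells in MDS. In the other 3 comparisons of cell types other splits were as large. Many of the 40 splits keep libraries of 1 donor together, unlike the real groups, so they do not exclude chance for any of the comparisons. For healthy CD141Hi against CD34 cells the 3 other splits as large gave 2576 to 7831 genes, several times the real number, which points to a structure of the samples. None of these 3 parts the libraries of every donor, and the 19 other splits that do gave at most 0. Such splits gave at most 43 and 3 in the other healthy comparisons, and the 15 in MDS at most 23, 8 and 33. Libraries of 1 donor are alike, and these 19 and 15 splits, with the real one added, are too few for a share under 0.05.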

How the results depend on the processing

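Tests without 1 healthy donor's 3 libraries, without the 5 libraries with counts in the most genes, and with or within the classes by pseudogene share were chosen after the data had been seen. Numbers of genes past the threshold (higher and lower together) are listed in a fixed order: MDS against healthy donors in CD141Hi, CD1c and CD34 cells, then CD141Hi against CD34, CD1c against CD34 and CD141Hi against CD1c cells in healthy donors and again in MDS, then the 3 differences of the MDS effect in the same order of cell types. In all libraries these were 0, 0, 0, 126, 65, 1, 242, 90, 7, 0, 0, 0. With DESeq2 size factors they were 0, 0, 0, 86, 49, 1, 152, 53, 0, 0, 0, 0, with the DESeq2 Wald test 12780, 1201, 8451, 305, 386, 77, 2039, 813, 1448, 516, 94, 467, with limma-voom 123, 5, 19, 2773, 2703, 6635, 843, 1788, 231, 65, 8, 25, with no filter 67, 14, 3, 238, 244, 61, 744, 388, 282, 61, 10, 79, and with a minimum count of 50 0, 0, 0, 146, 54, 1, 420, 68, 23, 0, 0, 0. With the number of genes detected as a covariate they were 126, 0, 0, 80, 43, 0, 629, 579, 157, 0, 0, 0. Fitting only the 2 groups compared, which leaves fewer libraries to estimate spread, gave 0, 0, 0, 18, 298, 5, 55, 109, 0 for the first 9. With the donor as a replicate block the 6 comparisons of cell types and the 3 differences gave 216, 168, 10, 251, 176, 4, 0, 0, 0. With the number shared by a healthy donor and a patient as a replicate block, a number that names different people, MDS against healthy donors gave 0, 2, 0.

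Without that donor the numbers were 0, 1, 0, 383, 278, 23, 581, 188, 3, 0, 0, 0, and 1310, 111, 1966, 1269, 950, 971, 2752, 1355, 2518, 447, 71, 472 with the DESeq2 Wald test. Without the 5 libraries they were 0, 0, 0, 267, 148, 17, 648, 169, 7, 0, 0, 0. With the class as a term they were 11186, 0, 6169, 135, 54, 2, 302, 111, 10, 0, 0, 0, with that term and without that donor 0, 1, 0, 408, 306, 36, 605, 226, 8, 0, 0, 0, and by limma-voom in the same setting 20, 0, 1, 2245, 2205, 1762, 853, 1953, 189, 4, 1, 12. Within the high class alone they were 0, 0, 0, 2, 0, 1, 411, 94, 51, 1, 0, 0, and within the low class alone, which holds 1 patient and thus assumes that the lone MDS libraries vary like the others, 0, 0, 1, 175, 153, 35, 0, 0, 0, 0, 0, 0. Leaving out 1 library at a time gave 0 to 5 in CD141Hi and 0 to 1 in CD34 cells for MDS against healthy donors, and 0 throughout in CD1c cells. For the cell types it gave 49 to 284, 20 to 70, 0 to 7, 92 to 338, 31 to 181, 0 to 49 in the order above, and for the 2 differences of the MDS effect that involve CD141Hi cells 0 to 7 and 0 to 7. The cause of these changes was not tested. DESeq2 size factors moved the median log2 fold change of all genes from -0.22, 0.04, -0.24, -0.49, 0.55, -1.43 to -0.04, -0.0044, -0.0021, -0.52, 0.47, -1.39 in the 6 comparisons of cell types, and from -3.27, -1.84, -1.81 to -4.13, -2.43, -2.33 between MDS and healthy donors.

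Of the lists in the 9 comparisons and 3 differences, 205 passed with the preset correlation and 35 with the estimated one. Without the 3 libraries 29 passed with the estimated correlation, and without the 5 libraries 134 with the preset one. Within donors 142 passed, 35 with the estimated correlation and 29 with it and without the 3 libraries. Of the 68 list results given above, 30 lost their call with the estimated correlation, 9 with the covariate and 9 without the 5 libraries, while all 45 that could be tested with the donor as a replicate block kept direction and side of the threshold. Relative to all genes, the median of cDC1 markers in MDS CD141Hi cells turned negative with the covariate (-1.84), without the 3 libraries (-0.72), without the 5 (-0.90) and without the 3 with the class as a term (-0.50), and ranged from -0.45 to 1.72 without 1 library. The test direction turned for ribosomal protein genes in CD141Hi cells with the covariate (median -0.38), for immediate-early genes in CD141Hi cells likewise (-1.21), for immediate-early genes in CD34 cells without the 5 libraries (0.0247), and for glycolysis genes in CD1c cells with the covariate (-0.15), without the 3 libraries (0.26, with either correlation), without the 5 (-0.18) and without the 3 with the class as a term (0.33). Without 1 library, oxidative phosphorylation in healthy CD141Hi against CD1c cells ranged from -0.18 to 2.47, stem and progenitor markers in MDS against healthy CD1c cells from -0.08 to 1.54 and T and NK cell genes in MDS CD141Hi against CD34 cells from -0.63 to 1.57. The cause was not tested.

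Of the 87 calls of genes chosen by smallest p, 52 kept theirs with only the 2 groups fitted, 47 within the high class, 30 within the low class, 68 with the donor as a replicate block and 78 without the 3 libraries. Within the low class the MDS log2 fold change was -2.75 for IRF4 in CD141Hi against CD34 and 0.89 for CXCL3 in CD141Hi against CD1c cells, opposite to all libraries. These values rest on 0 to 2 counts in 1 MDS library of each cell type and the prior count, so no direction is read from them. Calls of named genes and lists not given as lost with the donor as a block were kept. None of the 12 tests of library measures passed with medians or without the 3 libraries. With so few libraries that does not show that the measures are alike. Depth limits genes near 0 in most libraries, for which fitted fold changes rest on the prior count.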

Other observations

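Some further gene groups differed between cell types. Basophil and mast cell genes were lower in CD1c than CD34 cells in healthy donors (13 of 15 below 0, median log2 fold change -2.86, adjusted p = 3.61e-10, and 0.0272 with an estimated correlation, lower in 5 of 6 donors) and in MDS (13 of 15, -2.76, adjusted p = 9.02e-09, and 0.0343 with an estimated correlation, lower in 5 of 5 patients). Genes of the AXL SIGLEC6 dendritic cell were higher in MDS CD1c than CD34 cells (9 of 10, 1.94, adjusted p = 6.92e-05, and 0.0343 with an estimated correlation, higher in 5 of 5 patients).

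With the preset correlation, proliferation genes were also higher in CD141Hi than CD1c cells in healthy donors (25 of 30, median 0.53, adjusted p = 2.99e-06, and 0.497 with an estimated correlation) and in MDS (29 of 30, 0.97, adjusted p = 6.45e-06, and 0.482 with an estimated correlation). The estimated correlation ended both calls. No test of a further hypothesis was run.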
